A study of Zea mays with 192 samples.

How the data were processed

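Single maize leaf protoplasts, 96 transfected with a pool of pre-meiotic transcription factors and 96 with a pool of bHLH factors, were profiled with CEL-seq2, a method that counts the 3' ends of polyadenylated RNA with unique molecular identifiers (UMIs), per the labels' protocols. Reads were processed with HISAT2, SAMtools and UMI-tools on the maize build B73 RefGen v3, per the submitters' processing notes. Their versions, the gene annotation and any filter on cells are not given in the sources used here. The table has a row for each gene model, 80 rows for PHAS loci and 32 rows for GFP fusion constructs, and no row is 0 in every cell.

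The deposited values are named TPM by their file but were handled as a signal scaled by the authors, because their sums per cell run from 65502 to 10967874 instead of 1000000. Each value equals a UMI count times 1000000 divided by a cell's total, but the totals of the cells were recycled down the rows, so a value was mostly divided by the total of another cell. Multiplying back by the recycled totals gave whole numbers for 1001042 of 1001042 nonzero values (100%, within a tolerance of 0.001 UMI). The recovered sums of the cells matched the totals used as divisors within 2.51e-05 UMI. UMIs per 1000000 were then recomputed within each cell and are called TPM in the text. The design written before the data were examined assumed TPM as deposited and was kept otherwise, with the deposited values as they stand as an added alternative.

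Samples were grouped by the pool in their titles. Protoplast numbers only count cells. The labels name no separate transfections, so each pool is 1 replicate and no p-value, standard error or count of changed genes was made from cells. A cell was kept when at least 500 genes had a UMI, which kept all 96 in each pool. The assignment of construct rows to a pool was made from where their UMIs fell, after the values were seen: the rows of bHLH51, bHLH122, Ms23 and Ms32 to the bHLH pool and the other 23, GFP_bHLH97 and GFP_bHLH103 included, to the pre-meiotic TF pool. The GFP_control row was left out. No doublet caller was run, since the labels describe each sample as a single protoplast. No 2 cells had identical values, and the highest correlation between any 2 cells was 0.89. Depth ran from 953 to 148894 UMIs per cell. Shares of cells are given with exact Clopper-Pearson 95% intervals, ratios of summed UMIs with the interval from the exact binomial one, and folds against a pool with no UMI use a floor of 3 UMIs over the pool (0.99 TPM in the pre-meiotic TF pool and 0.92 TPM in the bHLH pool). All cover counting error only. To compare shares across depths, cells were thinned to 5000 UMIs, leaving out 10 shallower cells of the pre-meiotic TF pool and 1 of the bHLH pool.

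The between-pool ratio of a gene is the log2 of the mean TPM plus 10 in the bHLH pool over that in the pre-meiotic TF pool. The pseudocount shrinks the ratios of low genes. Eligible genes had a UMI in at least 25% of the cells and a mean of at least 50 TPM in at least 1 pool (1775 genes, 7 construct rows and 2 PHAS rows). The median log2 ratio of the eligible genes was 0.26, and ratios called centred are relative to it. Gene lists were fixed before the data were examined. A list's median was placed among 10000 random lists of eligible genes matched on mean expression in 20 bins. The reference table of the assembly Zm-B73-REFERENCE-NAM-5.0 gave a row for 16090 of the IDs and an informative name for 2205, and it has no descriptions, so most of the 23 fixed lists had too few eligible members. The lists of light harvesting, cytosolic ribosome, cell wall and organelle genes matched no row. For C4 mesophyll, detoxification, pre-meiotic anther regulators and small RNA machinery 1 member each was eligible, and the list of annotated transcription factors, with 6, was used only to find factors. None was eligible among the genes of the lists of tapetum, C4 bundle sheath, chlorophyll biosynthesis, epidermis, vascular, cell cycle, hypoxia, glycolysis or housekeeping genes. After the values had been seen, rows whose name belongs to another gene were taken out of 3 lists, 9 lists were added by gene name, and that of arabinogalactan and wall genes had 1 eligible member. No coordinates are given, since the build of the names differs from that of the data.

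The genes named are, by a rule fixed beforehand, the 12 highest and 12 lowest eligible rows by ratio whose share of cells differs in the same direction, the detected anther bHLH genes, the eligible genes of the small RNA machinery, the 5 PHAS loci detected in most cells of each pool, up to 20 pool-marking factors, 2 to 4 members per other list, and the 3 genes with the highest association with each of up to 6 pool-marking factors detected in 10% to 90% of their pool's cells. Such a factor is detected in at least 20% of the cells of a pool and in the other pool in a share at least 5 times lower. Genes with the highest and lowest ratios that did not mark a pool were added after the values were seen. Associations are partial Spearman correlations of TPM across the cells of a pool, given the rank of genes detected per cell, between factors that mark a pool (detected in at least 20% of its cells) and rows detected in at least 25% of cells, and percentiles are among the 500 genes nearest in detection share. Clusters came from Leiden clustering at resolution 1 on 15 nearest neighbours in 20 principal components of the 1000 most variable rows.

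Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9 was used. The steps were tested on simulated data with real depths. The recycled division was undone without error. Over 1352 simulated eligible genes, genes planted at log2 ratios of -2 and -1 (50 each) had median recovered ratios of -1.61 and -0.90, and those planted at 1 and 2 had 0.85 and 1.91. Of the unchanged genes, 99.6% lay within 0.5. Of 20 genes planted to follow a factor across 96 cells, 20 were the highest by partial correlation. There the factor's level was known without counting error and the planted genes were eligible ones. The test therefore does not tell whether an association of sparse construct rows with sparse PHAS loci would be found. Alternatives tried were pseudocounts of 1 and 100, averaging log2 values, leaving out the highest cell, a minimum of 2000 genes per cell or none, rescaling by the median of ratios of rows detected in at least 90% of cells, summed UMIs, no minimum on low values, at least 2 UMIs as detected, thinning, other correlations and other cluster settings. Added after seeing the data were the deposited values as they stand, TPM without the 2 most abundant rows, their share as a second covariate and thinning for the constructs.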

Results

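The series holds single protoplasts from leaves of etiolated B73 maize seedlings, a wild-type inbred line grown in darkness. Each protoplast had been transfected with one of 2 pools of transcription factor constructs. The first pool held factors active in anthers before meiosis, and the second held basic helix-loop-helix (bHLH) factors. The series holds no untransfected protoplasts. The design text states the purpose: putative regulators of anther phasiRNAs were expressed in a tissue where they are normally silent. PhasiRNAs are small RNAs cut at regular steps from long transcripts of PHAS loci, and maize anthers make a 21-nucleotide and a 24-nucleotide class. The sample descriptions name cells of the first pool 21merTFs and cells of the second pool 24merTFs. Polyadenylated RNA was counted by unique molecular identifiers (UMIs). Each pool had 96 protoplasts. The pre-meiotic TF pool gave 3029855 UMIs in all, with a median of 26488 per cell and a range of 953 to 88243. The bHLH pool gave 3274116 UMIs, with a median of 28578 and a range of 4699 to 148894. A median of 5070 genes was detected per cell in the pre-meiotic TF pool and of 5664.5 in the bHLH pool. Of the cells with fewer than 2000 genes, 22 were in the pre-meiotic TF pool and 2 in the bHLH pool. After thinning every cell to 5000 UMIs, the medians were 1392.5 genes over 86 cells and 1599 genes over 95 cells. The labels name no separate transfections, so each pool counts as 1 replicate. No difference between the pools has a replicate check, no significance test between the pools was made, and all intervals are 95% intervals that cover counting error only.

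Construct rows differed between the pools. The sources list no constructs per pool, so rows were assigned to a pool by where their UMIs fell. That assignment in part fixes the separation described here. Rows assigned to the bHLH pool were GFP fusions of Ms23, Ms32, bHLH51 and bHLH122. These 4 bHLH factors act in the development of the tapetum, the nutritive inner layer of the anther wall. Each was represented by 2 rows, one named with GFP after the factor and one with GFP first. bHLH51_GFP and bHLH122_GFP were each detected in 95 of 96 cells of the bHLH pool (99.0%, exact interval 94.3% to 99.97%), with mean levels of 703 and 729 TPM. In the pre-meiotic TF pool bHLH51_GFP had no UMI, which by a floor of 3 UMIs over the pool makes it at least 686-fold higher in the bHLH pool, and bHLH122_GFP had 1 UMI. Ms23_GFP was detected in 95.8% of the bHLH pool's cells and Ms32_GFP in 92.7%, at 270.3 and 220 TPM, and neither had a UMI in the pre-meiotic TF pool. The 4 rows with GFP first were detected in fewer cells, from 80.2% for GFP_bHLH122 to 53.1% for GFP_Ms23. A cell of the bHLH pool had UMIs on a median of 7 of the 8 rows.

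In the pre-meiotic TF pool the constructs were more numerous and most were sparser. To this pool 23 rows were assigned, some of them on weak grounds. GFP_EREB69 had 25 UMIs against 14 in the bHLH pool (bHLH over pre-meiotic ratio of summed UMIs 0.518, 0.249 to 1.036). ZFL2_GFP had 8 against 3 (0.347, 0.0593 to 1.446). The most widespread were GFP_bHLH97 (67.7% of cells, 88.5 TPM), GFP_bHLH103 (54.2%, 67.3 TPM) and GFP_OFP9 (53.1%, 41.8 TPM), followed by GFP_ZHD4 (37.5%) and GFP_NAC25 (36.5%). GFP_ABI5, GFP_TCP23, GFP_CSD4, GFP_DOF25, GFP_WRKY81, GFP_DOF7 and GFP_GBP15 lay between 20.8% and 30.2% of cells. These 12 rows met the rule for a factor that marks its pool, which asks for 20% of cells in one pool and a share at least 5 times lower in the other. All 8 bHLH rows met it too. Among the sparser rows were GFP_HSF2 (16 UMIs in 10 cells) and GFP_ZIM13 (14 UMIs in 11 cells), neither with a UMI in the bHLH pool. The median share of cells was 22.9% over the 23 rows and 86.5% over the 8 rows. Cells of the pre-meiotic TF pool had UMIs on a median of 5.5 of the 23 rows, with a range of 0 to 23. Summed over all construct rows, the median cell had 277 TPM in the pre-meiotic TF pool and 1988 TPM in the bHLH pool. Some rows had UMIs in the pool that was not theirs: 70 UMIs on the 23 rows in the bHLH pool against 1235 in their own, and 35 UMIs on the 8 rows in the pre-meiotic TF pool against 6591. GFP_bHLH122, with 22 of these 35 UMIs, was seen in 14.6% of pre-meiotic cells.

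**Figure D1:**
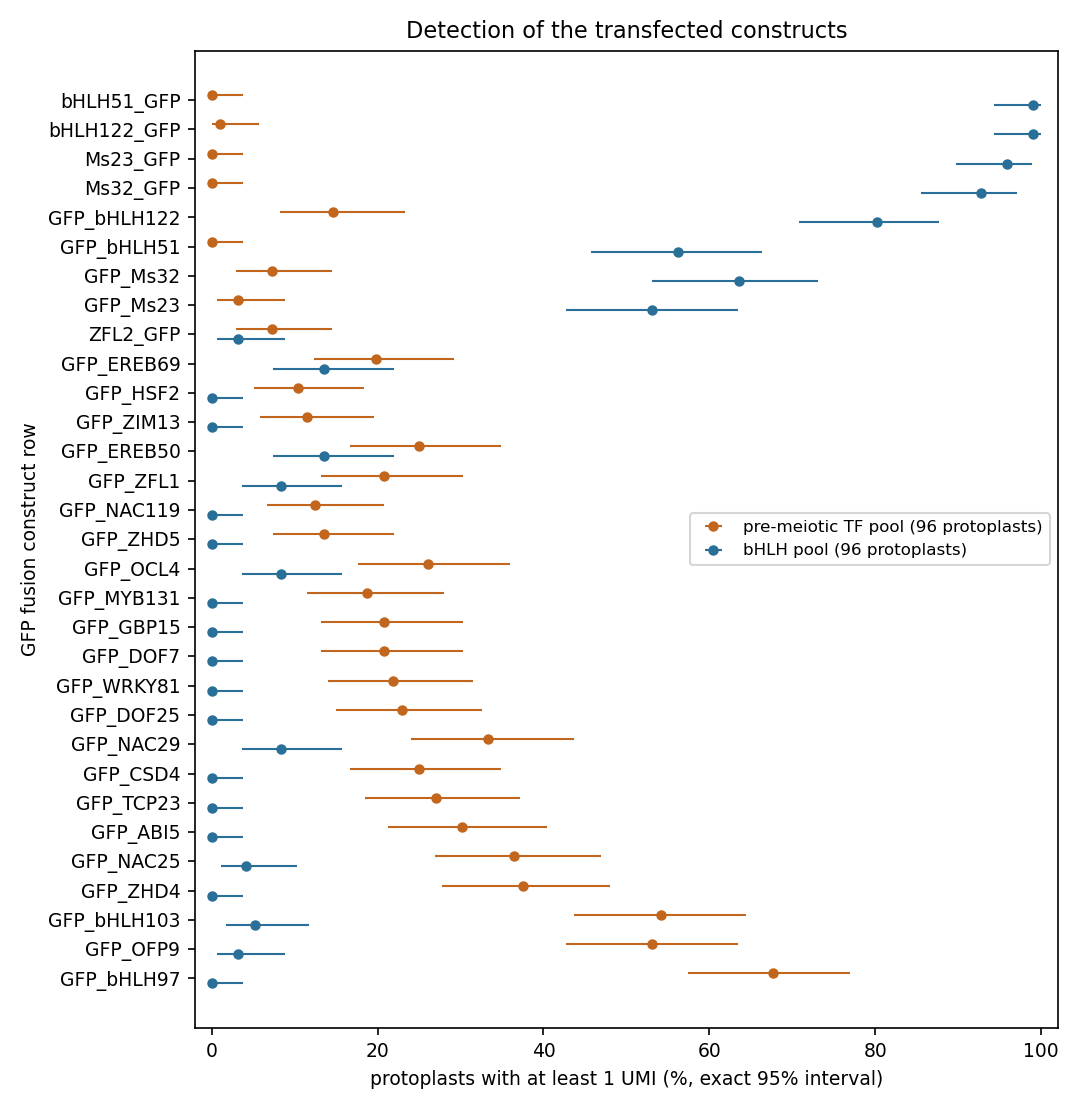
Share of protoplasts with at least 1 UMI (horizontal axis, percent) for each GFP fusion construct row, in the pre-meiotic TF pool and the bHLH pool, with 96 protoplasts each. Points are shares and bars are exact 95% intervals, which cover counting error only. The 8 rows of bHLH51, bHLH122, Ms23 and Ms32 lie between 53.1% and 99.0% in the bHLH pool and at or below 14.6% in the other.

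Among gene models of the maize genome, the widest gaps between the pools were on genes of factors named among the constructs, on OFP16 and on models without an informative name. The anther bHLH genes ms23 (GRMZM2G021276), ms32 (GRMZM2G163233) and GRMZM2G139372 had mean levels of 835.5, 1581 and 575 TPM in the bHLH pool. In the pre-meiotic TF pool ms23 and GRMZM2G139372 had no UMI, which makes them at least 815-fold and 563-fold higher in the bHLH pool, and ms32 had 1 UMI. AC233960.1_FG005, a model with no name in the table used here, had 1818 against 1.35 TPM. In the opposite direction, nam1 (GRMZM2G393433, also named NAC119) had 1065 TPM in the pre-meiotic TF pool and no UMI in the bHLH pool (at least 1008-fold higher). The same held for ocl4 (GRMZM2G123140), a homeodomain gene of the anther epidermis, with 745 TPM (at least 701-fold), for OFP16 (GRMZM2G055257), with 515 TPM (at least 477-fold), and for zfl1 (GRMZM2G098813), a maize homologue of LEAFY, with 201 TPM (at least 205-fold). The models without an informative name GRMZM2G438438, GRMZM2G108865, GRMZM2G120151, GRMZM2G036966, GRMZM2G378490, GRMZM2G301089 and GRMZM2G085964 completed this end of the range, with 155 to 790 TPM in the pre-meiotic TF pool and 0 to 4.25 TPM in the bHLH pool. CSD4 (GRMZM5G895313) was the twelfth, at 1163 against 77.3 TPM. The table has separate rows for a construct and for the gene model of the same factor. Construct rows exist for NAC119, OCL4, ZFL1, CSD4, Ms23 and Ms32. They exist for bHLH51 and bHLH122 as well, whose gene models were not identified by name here. Whether RNA of a construct was also counted on the gene model's row was not tested. The gaps on gene models of transfected factors therefore do not show that the native genes were active.

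Beyond the factors, ratios are given relative to the median of 1775 eligible genes, which lay at a log2 ratio of 0.26 (bHLH pool over pre-meiotic TF pool, mean TPM plus 10). Before centring, the quartiles of these log2 ratios were -0.36 and 0.70. A single unnamed model, GRMZM2G028910, took a median of 30.8% of a cell's UMIs in the pre-meiotic TF pool (quartiles 23.0% and 39.6%) and 21.7% in the bHLH pool (quartiles 17.8% and 26.1%).

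Among the single genes with the highest ratios beyond the factors were 2 with a heat shock name. The small heat shock gene hsp18 (GRMZM2G149647, also named hsp26) had 1897 TPM in the bHLH pool against 204 in the pre-meiotic TF pool, a centred log2 ratio of 2.89, and was seen in 100% against 77.1% of cells. The heat shock factor gene Hsf05 (GRMZM2G133023) had 150.3 against 30.9 TPM (1.71). Unnamed models filled most other places: GRMZM2G437100 (4379 against 577 TPM, 2.64), GRMZM2G118624 (118 against 2.88 TPM, 3.05, with a ratio of summed UMIs of 20.4, 12.2 to 36.9) and GRMZM2G468111 (322 against 50.4 TPM, 2.20). dcl1 (GRMZM2G040762), which encodes the Dicer-like enzyme that makes microRNAs, was the sole member of the small RNA machinery list to reach the expression minimum. It had 58.7 TPM in the bHLH pool and 7.58 TPM in the pre-meiotic TF pool. Summed UMIs, 164 against 36, gave a smaller ratio of 4.22 (2.92 to 6.23). It was detected in 71.9% (61.8% to 80.6%) against 29.2% (20.3% to 39.3%) of cells. Thinned to 5000 UMIs, these shares were 30.5% and 5.81%.

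On the pre-meiotic side, the genes with the lowest ratios that did not mark a pool included In2-2 (GRMZM2G020631), a gene known from its response to herbicide safeners, at 528 against 55.6 TPM (-3.30), and the dehydrin gene dhn2 (GRMZM2G373522) at 269 against 44.2 TPM (-2.63). The unnamed models GRMZM2G127379 (293 against 15.5 TPM, -3.84), GRMZM2G073548 (307.5 against 25.1 TPM, -3.44) and GRMZM2G159500 (510 against 52.0 TPM, -3.33) lay in the same range. This second ranking, of genes that did not mark a pool, also gave Hsf05 and GRMZM2G468111 and was added after the values were seen.

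Of the gene lists fixed before the data were examined, 4 had at least 3 eligible members, apart from the list of annotated transcription factors (6 eligible), which was used only to find factors. Of 49 matched members of the wound and defence list, 7 reached the expression minimum, and these 7 were lower in the bHLH pool than the median gene. Their median was -1.84, at the 0.05th percentile of 10000 random lists matched on expression. With a pseudocount of 100 it was -0.74. Over all 49 with no minimum the median was -0.16. That value is relative to the median of all gene models with a UMI, not of the eligible genes. chiI (GRMZM2G145461), a chitinase gene, had 128 TPM in the pre-meiotic TF pool and 17.4 TPM in the bHLH pool (ratio of summed UMIs 0.0874, 0.0606 to 0.1225). The wound-induced protease inhibitor gene wip1 (GRMZM2G156632) had 427 against 121 TPM, the pathogenesis-related gene pr5 (GRMZM2G402631) 247 against 76.1 TPM, and the jasmonate repressor gene TIFY15 (GRMZM2G005954) 62.3 against 5.86 TPM. The heat shock list had 4 of 5 members above the median gene and a median of 0.61, at the 83.2th percentile. Its members included HSP90-1 (GRMZM2G024668; 839 against 327.5 TPM) and hsp70-4 (GRMZM2G340251; 1491 against 703 TPM), and hsp1 (GRMZM5G802801) lay at -0.99. The 3 members of the proteasome and ubiquitin list, all named ubiquitin, had a median of 0.86 (89.2th percentile), with 2 of 3 above the median gene. The anther bHLH list is described with the factors above. Its 3 members had a median of 6.14. The ratio of summed UMIs of ms32 was 4473 (802.5 to 176725). The lower ends of the exact intervals of the 3 members, which are not the 3-UMI floors, had a median of 662-fold.

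Further lists were built from gene names after the values had been seen. Of 12 heat shock protein genes, 10 lay above the median gene, with a median of 0.71 (98.0th percentile). hsp18f (GRMZM2G083810) had 2420 against 880 TPM and hsp82 (GRMZM5G833699) 541 against 166 TPM. Of 6 autophagy genes, 5 lay above, with a median of 0.82 (99.7th percentile), and atg9 (GRMZM2G035461) had 57.1 against 14.1 TPM. Glutathione S-transferase genes, whose products conjugate toxic compounds, went the other way. Of 10 such genes 1 lay above the median gene, and the median was -1.26 (0.01th percentile). gst6 (GRMZM2G129357) had 22.3 TPM in the bHLH pool against 141.5, and gst31 (GRMZM2G475059) had 219 against 850, while gst24 (GRMZM2G032856) lay at 0.98. Of 19 matched genes of protein folding in the endoplasmic reticulum 6 were eligible, and these lay below the median gene, with a median of -1.45 (0.31th percentile) that was -0.049 over all 19 with no minimum. Among the 6 were the calnexin gene CNX (GRMZM2G022180; 106.5 against 290 TPM) and the calreticulin gene crt2 (GRMZM2G358059; 15.1 against 68.3 TPM). All 7 genes of the defence protein list, 4 of them shared with the fixed wound and defence list, lay below, at a median of -1.43. With no minimum on low values, the medians were -0.69 for the 16 matched defence protein genes, -0.57 for the 25 glutathione S-transferase genes and -0.098 for the 44 genes of the jasmonate list. All medians with no minimum, that of endoplasmic reticulum folding included, are relative to the median of all gene models with a UMI. With a pseudocount of 100 the medians were -0.73 for the glutathione S-transferases, -0.74 for endoplasmic reticulum folding, -0.49 for the defence proteins and 0.31 for autophagy. The jasmonate list took in opr genes by name alone, and whether their products make jasmonate was not checked. Of its 7 eligible genes 6 lay below the median gene, and opr2 (GRMZM2G000236; 5899 against 2289 TPM) lay above. opr3 (GRMZM2G156712) had 8.87 against 52.4 TPM (ratio of summed UMIs 0.105, 0.0618 to 0.1696), and the list median was -0.97 (3.36th percentile). Translation genes (18 members, median 0.11, 80.2th percentile) and glycolysis genes (8 members, median -0.56, 11.1th percentile) lay inside the range of random lists. When the deposited values were averaged without rescaling, 5 members whose centred ratio exceeded the margin of counting error of their summed UMIs changed sign. They were hsp1 (GRMZM5G802801), hsp22 (GRMZM2G007729), WRKY43 (GRMZM2G148087), eno1 (GRMZM2G064302) and the ubiquitin gene GRMZM2G118637. Before centring, hsp22 was already higher in the bHLH pool (ratio of summed UMIs 1.094, 1.055 to 1.133).

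**Figure D2:**
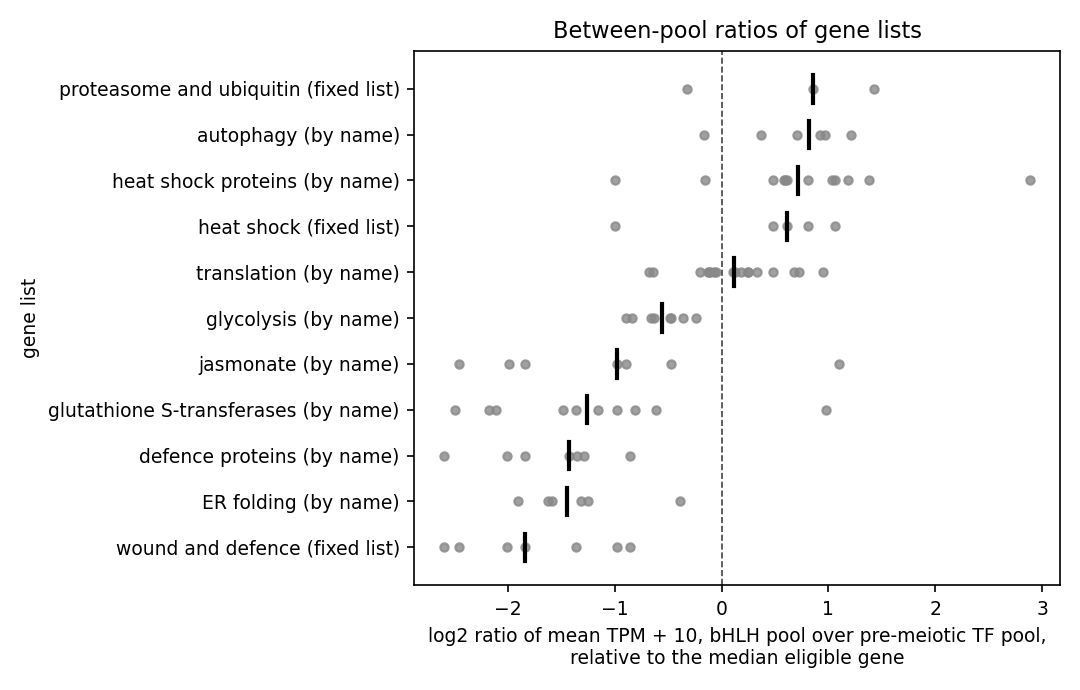
Log2 ratio of mean TPM plus 10, bHLH pool over pre-meiotic TF pool, relative to the median eligible gene (horizontal axis), for the members of each gene list. Grey points are genes and black bars are list medians, from -1.84 for the wound and defence list to 0.86 for the proteasome and ubiquitin list. The anther bHLH list is not drawn.

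Markers of leaf cell types ranged from a gene of the mesophyll list seen in most cells to genes seen in few. Pyruvate orthophosphate dikinase (ppdk1, GRMZM2G306345, also named cyppdkZm1), on the C4 mesophyll list, was detected in 73 cells of the pre-meiotic TF pool and 70 of the bHLH pool, at 138 and 88.4 TPM. The form of its transcript was not determined, so its detection alone does not mark C4 mesophyll cells. The mesophyll genes pep1 (GRMZM2G083841) and GRMZM2G121878 were each detected in 16 and 7 cells, and mdh6 (GRMZM2G129513) in 11 and 3. All 4 mesophyll genes were thus seen in fewer cells of the bHLH pool, pep1, GRMZM2G121878 and mdh6 on few UMIs. The bundle sheath gene me3 (GRMZM2G085019) was detected in 24 and 25 cells. The epidermal gene ocl1 (GRMZM2G026643) was detected in 37 and 53 cells. The tapetum genes ms26 (GRMZM2G091822) and ms8 (GRMZM2G119265) had no UMI in the pre-meiotic TF pool and 1 UMI each in the bHLH pool, so neither was measurably active in either pool at this depth. Other genes of the small RNA machinery were also sparse: 1 of 3 models named dcl4 (GRMZM2G160473) was seen in 22 and 23 cells, argonaute1 (GRMZM2G162525) in 15 and 24, and rdr6 (GRMZM2G145201) in 8 and 5. The catalase gene cat1 (GRMZM2G088212), the eligible member of the detoxification list, was seen in 78 and 89 cells, at 108.5 and 149 TPM.

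PHAS transcripts were present in both pools. Of 80 PHAS rows, 44 belonged to the 21-nucleotide class and 36 to the 24-nucleotide class. At least 1 UMI of a 24-PHAS locus was seen in 89 of 96 cells of the pre-meiotic TF pool (92.7%, 85.6% to 97.02%) and in 94 of 96 cells of the bHLH pool (97.9%, 92.7% to 99.7%), with mean sums of 299 and 309 TPM. For the 21-PHAS loci the shares were 71.9% (61.8% to 80.6%) and 76.0% (66.3% to 84.2%), with 118 and 87.1 TPM. After thinning to equal depth the order of these shares turned, to 44.2% and 36.8%, while those of the 24-PHAS loci were 70.9% and 78.9%. Most rows were nearly empty. In the pre-meiotic TF pool 22 of the 44 rows of 21-PHAS loci had any UMI, and 9 of these had it in a single cell. In the bHLH pool 40 rows had a UMI, 27 of them in a single cell. For 24-PHAS loci these numbers were 20 and 9 in the pre-meiotic TF pool, and 27 and 17 in the bHLH pool.

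A single locus, 24PHAS_NO166, supplied 59.3% of all 24-PHAS UMIs. It was detected in 85.4% (76.7% to 91.8%) of pre-meiotic cells and 92.7% (85.6% to 97.02%) of bHLH cells, at 169 and 195 TPM, and summed UMIs gave a ratio of 1.12 (0.99 to 1.26), an interval that includes no difference. After thinning it was seen in 55.8% and 62.1% of cells. 24PHAS_NO63 was detected in 67.7% and 68.8% of cells, at 70.8 and 55.6 TPM (ratio 0.77, 0.63 to 0.945), and after thinning in 33.7% and 20.0%. 24PHAS_NO269 had 22.7 and 20.6 TPM (ratio 1.03, 0.74 to 1.46) and was seen in 42.7% and 45.8% of cells, and after thinning in 11.6% and 9.47%. 24PHAS_NO156 was detected in 28.1% (19.4% to 38.2%) and 44.8% (34.6% to 55.3%) of cells, and after thinning in 10.5% and 11.6%. It had 13.95 and 18.6 TPM, and its ratio of 1.32 (0.86 to 2.03) includes no difference. 21PHAS_NO588 and 21PHAS_NO589 held the same number of UMIs in nearly every cell, 161 and 160 in all, and stand for 1 signal. 21PHAS_NO588 was detected in 51.0% and 40.6% of cells, at 30.2 and 16.0 TPM (ratio 0.64, 0.46 to 0.89), and after thinning was seen in 14.0% and 8.42%. Ratios of summed UMIs in this paragraph are not relative to the median gene, unlike the centred ratios of genes and lists. Centred log2 ratios of mean TPM were -0.064 for 24PHAS_NO166, -0.57 for 24PHAS_NO63 and -0.36 for 24PHAS_NO269. They were -0.009 for 24PHAS_NO156 and -0.89 for 21PHAS_NO588. Outside the naming rule, and chosen after their values were seen, 21PHAS_NO380 had 24 UMIs in the pre-meiotic TF pool and 60 in the bHLH pool (ratio 2.31, 1.42 to 3.88), and 21PHAS_NO341 had 36 and 22 (ratio 0.57, 0.32 to 0.99). After thinning, 21PHAS_NO380 was seen in 8.14% and 6.32% of cells.

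**Figure D3:**
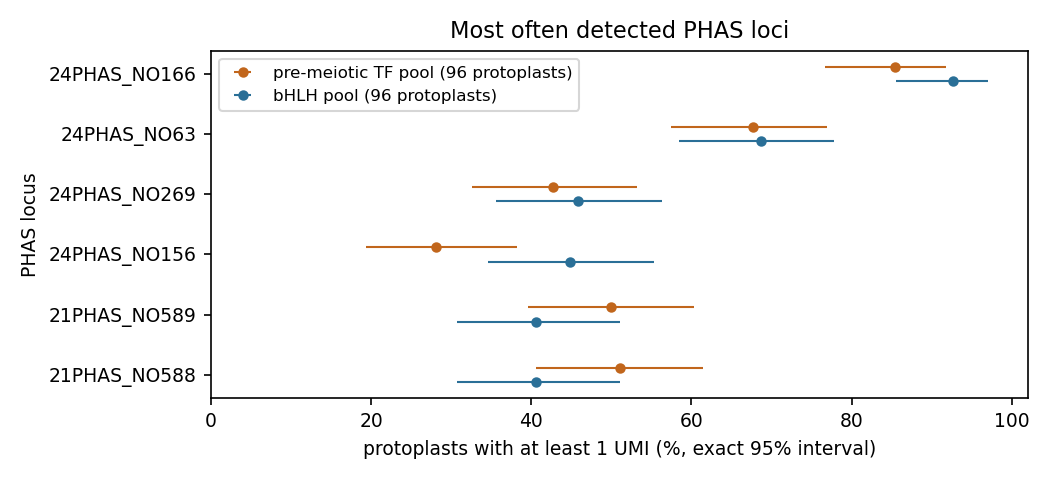
Share of protoplasts with at least 1 UMI (horizontal axis, percent) for the PHAS loci detected in most cells, in the pre-meiotic TF pool and the bHLH pool, with 96 protoplasts each. Points are shares and bars are exact 95% intervals, which cover counting error only. 24PHAS_NO166 lies at 85.4% and 92.7%, and its intervals overlap.

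Factor levels were compared with PHAS levels from cell to cell within a pool. The measure was a partial Spearman correlation given the number of genes detected. Over 64 pairs of 8 construct rows and 8 PHAS loci in the bHLH pool the median was -0.01, with a range of -0.26 to 0.24, and 30 pairs lay above 0. Over 84 pairs of 12 rows and 7 loci in the pre-meiotic TF pool the median was 0.03, with a range of -0.17 to 0.38, and 50 pairs lay above 0. The loci in these counts include 21PHAS_NO588 and 21PHAS_NO589, which stand for 1 signal. The highest values were 0.38 for GFP_OFP9 with 24PHAS_NO269, 0.32 for GFP_TCP23 with 24PHAS_NO156, and 0.31 and 0.30 for GFP_bHLH97 with 21PHAS_NO589 and 24PHAS_NO166. The lowest was -0.26 for GFP_bHLH122 with 24PHAS_NO166. Cells of 1 pool are not independent replicates, so these values carry no p. Plain correlations of the deposited values, which keep differences in depth between cells, had medians of 0.22 in the pre-meiotic TF pool and 0.27 in the bHLH pool.

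**Figure D4:**
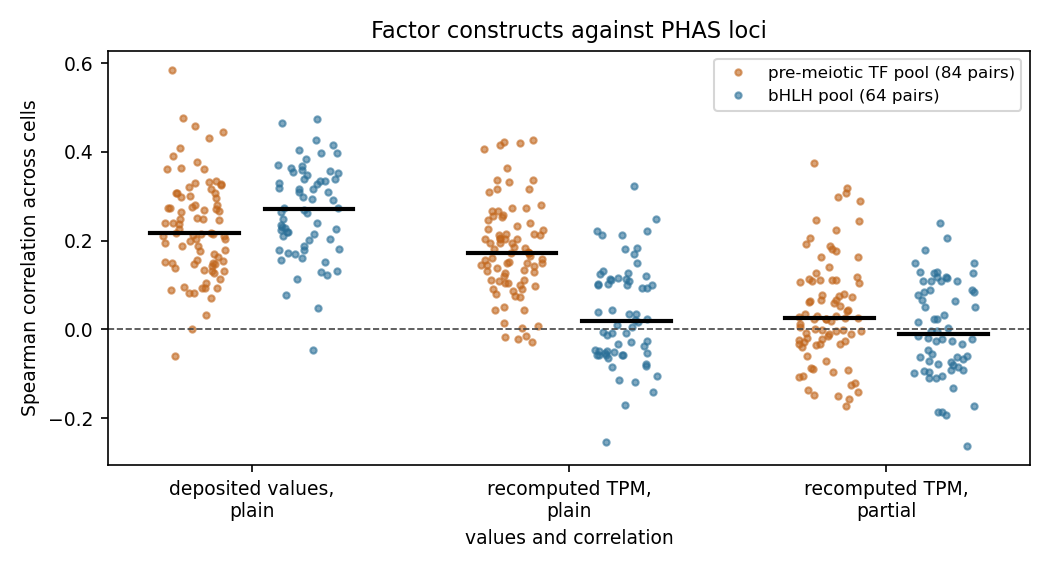
Spearman correlation across cells between factor construct rows and PHAS loci (vertical axis), for 84 pairs in the pre-meiotic TF pool and 64 pairs in the bHLH pool. Points are pairs and black bars are medians: 0.22 and 0.27 with the deposited values, 0.17 and 0.02 with recomputed TPM, and 0.03 and -0.01 with recomputed TPM given the number of genes detected.

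The median correlation among construct rows was above 0 in each pool. Some rows with GFP first held UMIs in the same cells. Matched UMIs are the smaller of the 2 counts in each cell, summed over cells, and do not identify shared molecules. In the pre-meiotic TF pool GFP_NAC29 (64 UMIs) had 28 matched on GFP_OCL4 (42 UMIs) and 27 on GFP_ZFL1 (32 UMIs). All 22 UMIs of GFP_bHLH122 there were matched on GFP_bHLH103, which had 190. Over 66 pairs of rows in the pre-meiotic TF pool the median partial correlation was 0.23, and it was highest for GFP_TCP23 and GFP_DOF25 (0.55). Over 28 pairs in the bHLH pool the median was 0.26, and it was highest for bHLH122_GFP and Ms23_GFP (0.72). The genes that followed single factors most closely were in part other factors. For GFP_bHLH97 they were CSD4 (GRMZM5G895313, 0.62), GRMZM2G120151 (0.60) and zfl1 (GRMZM2G098813, 0.58), and for GFP_bHLH103 they were zfl1 (0.55), GRMZM2G036966 (0.53) and GRMZM2G438438 (0.46), out of 7312 rows compared. For GFP_bHLH122 they were GRMZM2G458665 (0.47), GRMZM2G104979 (0.43) and AC233960.1_FG005 (0.41), out of 8282 rows. The highest values were 0.445 for GFP_Ms32 with GRMZM2G053239, 0.41 for GFP_bHLH51 with GRMZM2G178460 and 0.46 for GFP_Ms23 with GRMZM2G093272. GFP_Ms32 was followed next by GRMZM2G436199 (0.41) and GRMZM2G314656 (0.40), GFP_bHLH51 by GRMZM2G109165 (0.41) and GRMZM2G474326 (0.40), and GFP_Ms23 by GRMZM2G154218 (elfa3, 0.38) and GRMZM2G015097 (0.37).

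Clustering, from which the construct rows were not left out, split the cells by pool. Of 5 clusters, 2 held bHLH cells alone, 59 and 37, and 3 held pre-meiotic cells alone, 49, 27 and 20. Within each pool, depth differed between clusters. The 2 clusters of bHLH cells had medians of 6625 and 2912 genes per cell, and those of pre-meiotic cells 6692, 1508 and 5226. No cluster had a fixed cell type marker among its 10 leading genes, and none was given a cell type name.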

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

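The GFP_control row, which belongs to neither pool of factors, had 7 UMIs in the pre-meiotic TF pool and 5 UMIs in the bHLH pool, in as many cells each. These are above the 3 UMIs that a count of 0 allows. The row is not used in the comparisons, and no explanation was tested for it.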

How the results depend on the processing

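The direction of each gene list's median held under all the alternatives run, the translation list aside, though sizes moved. The translation median of 0.11 was smaller than its spread of 0.19 over random lists, so a change of its sign would not have been flagged. The alternatives using the deposited values, thinning of constructs, TPM without the 2 most abundant rows and their share as a covariate were chosen after seeing the data. The median log2 ratio of all eligible genes, to which ratios are centred, ran from -0.16 to 0.49. Of 132 list medians under alternatives 115 stayed within their spread and 17 did not. With a pseudocount of 100 the anther bHLH list was at 3.10, wound and defence at -0.74, glutathione S-transferases at -0.73, endoplasmic reticulum folding at -0.74, autophagy at 0.31 and defence proteins at -0.49, since a larger pseudocount shrinks ratios. With a pseudocount of 1 the anther bHLH list was at 9.41. With no minimum on low values, wound and defence was at -0.16 over 49 genes, glutathione S-transferases at -0.57, endoplasmic reticulum folding at -0.049, jasmonate at -0.10 and defence proteins at -0.69, which adds genes near 0 UMIs. This setting also changes the reference, to the median of all gene models with a UMI. With the deposited values the anther bHLH list was at 7.09, proteasome and ubiquitin at 1.95, defence proteins at -2.11, translation at 0.49 and glycolysis at -0.99. Averaged so, 5 genes whose centred ratio exceeded the margin of counting error of their summed UMIs reversed. These were hsp1 (GRMZM5G802801) to 0.42, WRKY43 (GRMZM2G148087) to 0.59, ubiquitin (GRMZM2G118637) to 0.67, hsp22 (GRMZM2G007729) to 0.84 and eno1 (GRMZM2G064302) to 0.57. Deposited and recomputed values hold the same UMI counts and differ only in the totals used as divisors, so these reversals come from that division. Of 1440 ratios of named items, 1120 stayed within their spread, 315 moved beyond it and 5 reversed. Translation genes and PHAS loci near 0 changed sign under several settings.

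Shares of cells depend on depth. Thinned to 5000 UMIs, cells had medians of 1392.5 and 1599 genes, 21-PHAS loci were seen in 44.2% and 36.8% of cells and 24-PHAS loci in 70.9% and 78.9% (pre-meiotic TF pool first), which turns the order of the 21-PHAS shares. With at least 2 UMIs, 24-PHAS loci were seen in 81.3% of pre-meiotic cells and 21-PHAS loci in 62.5% of bHLH cells. The median share over construct rows was 7.29% and 75.5% with at least 2 UMIs, and 5.81% and 48.9% after thinning. The median correlation of factors and PHAS loci was 0.172 in the pre-meiotic TF pool as a plain correlation, and 0.218 there and 0.271 in the bHLH pool with the deposited values. With these, GFP_bHLH122 and 24PHAS_NO166 reversed to 0.173, GFP_bHLH51 and 24PHAS_NO63 to 0.169, and GFP_bHLH51 and 21PHAS_NO588 to 0.200. Of 189 named correlations 168 stayed within their spread. Clusters numbered 10 at a resolution of 2. No paired analysis was possible because the protoplast numbers count single cells, no comparison of the pools comes from a significance test, and cells of the same number did not deviate together (median correlation 0.0103, against -0.00307 for other numbers).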

Other observations

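Within the bHLH pool, cells with more construct RNA also had more UMIs per 1000000 on the anther bHLH genes ms32, ms23 and GRMZM2G139372. The same held for AC233960.1_FG005, a model with no name in the reference used here. The partial correlation with the summed constructs was 0.83 for ms32 (GRMZM2G163233), 0.78 for ms23 (GRMZM2G021276), 0.73 for AC233960.1_FG005 and 0.72 for GRMZM2G139372. Whether construct RNA was counted on the gene-model rows of transfected factors was not tested. Next came the unnamed models GRMZM2G123212 (0.67) and GRMZM2G097135 (0.56), HSP90-1 (GRMZM2G024668, 0.54), the unnamed models GRMZM5G873926 (0.49) and GRMZM2G074404 (0.48), and hsp82 (GRMZM5G833699, 0.46). The same correlations in the pre-meiotic TF pool, with its own constructs, were 0.29 for GRMZM2G123212, -0.05 for HSP90-1 and 0.04 for hsp82. In that pool the highest were zfl1 (GRMZM2G098813, 0.70), OFP16 (GRMZM2G055257, 0.64), GRMZM2G036966 (0.61) and ocl4 (GRMZM2G123140, 0.61). As lists, glutathione S-transferases had a median of -0.18 in the bHLH pool and -0.03 in the pre-meiotic TF pool, and glycolysis genes -0.17 and 0.07. The wound and defence list had a median of 0.26 in the pre-meiotic TF pool (99.9th percentile of random lists) and of -0.06 in the bHLH pool.

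All tests that follow were chosen after the results they examine had been seen. UMIs of bHLH rows appeared in the pre-meiotic TF pool, and UMIs of pre-meiotic rows in the bHLH pool. Carry-over between the pools would spread them by abundance, but 2.86% of the 35 bHLH-row UMIs in the pre-meiotic TF pool (0.0723% to 14.9%) were on rows with GFP after the factor, which held 89.2% in their own pool. Reads shared among rows with GFP first may account for them: of 67 UMIs on 8 foreign rows in the bHLH pool, 98.5% were matched by as many UMIs on another foreign row of the same cell, against at most 62.7% in 1000 shuffles. This test replaced a first version that counted matches on any row and was saturated. No biological explanation was tested.

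In the deposited values, factors and PHAS loci were positively correlated in the bHLH pool, with a median of 0.271. The recycled totals leave the depth of a cell in those values, and this may be the source there: on recomputed TPM the median plain correlation was 0.0198. The median partial correlation on recomputed TPM was -0.00970, lower than 0.271 by more than the SD over pairs of 0.109. A joint rise of factors and PHAS loci as large as 0.271 was thus not seen. Since that value itself carries depth, the test cannot exclude a weaker joint rise. In the pre-meiotic TF pool the plain median on recomputed TPM was 0.172, and given the number of genes detected it was 0.0257.

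The heat shock protein list built by name after the values were seen was higher in the bHLH pool. The 7 eligible genes of the wound and defence list were lower. With no minimum on low values, all 49 matched genes had a median of -0.16 relative to all gene models with a UMI. The heat shock list fixed beforehand, at the 83.2th percentile, lay inside the random range. With at least 2000 genes per cell the medians of the list by name and of the 7 genes were 0.83 and -1.86, which argues against shallow cells as the whole cause. Leaving out the 2 most abundant rows (0.77 and -1.89) moved 0 of 144 named ratios beyond their spread after centring, so it decides nothing and a few rows stay open. The level of the bHLH constructs may be involved: within the bHLH pool the heat shock list's correlation with it lay at the 99.91th percentile of random lists, but wound and defence lay at the 3.715th, short of the 2.5th that the test asked for, and in the other pool the list by name lay at the 99.94th while the heat shock list fixed beforehand lay at the 97.4th in the bHLH pool and at the 35.0th in the other. The pre-meiotic TF pool also held a row named for a heat shock factor, GFP_HSF2, seen in 10 cells, and its part was not tested. A difference in preparation between the pools cannot be told apart from the factors, since the labels name no separate transfections within a pool. That 100% of cells lay in clusters of their own pool (99.5% with 2000 variable genes) decides nothing, as the construct rows were not left out of the clustering.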
